A study of Homo sapiens with 12 samples.

How the data were processed

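The series holds 12 samples in 6 groups of 2 libraries: control and AP20187 libraries of K562, of HepG2 and of K562 with PMA. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, cells were infected at a multiplicity of infection of 0.5. Puromycin selection began 2 days after infection and lasted 5 days. Cells were then divided into a control portion and a portion given 1 nM AP20187. Inserts were amplified from genomic DNA, and the PCR products were size-selected before sequencing on a MiSeq, or on a HiSeq 4000 for the PMA screens. Nothing in the labels says whether the 2 replicates came from separate infections.

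The deposited files are 3 lists of genomic regions, 1 per condition, each named by the descriptions of all 4 libraries of its condition. Replicates were thus pooled before deposit. Per the labels, reads were aligned with Bowtie, and the submitters' processing notes name HTSeq, MAGeCK and, for 8 of the 12 samples, the build hg19. Versions, settings and the order of steps are not given in the sources used here. The deposited lists carry an FDR of 0.01 in their names, and no value by which regions could be ranked. The lists have a chromosome, a start, an end and a whole number for each region. That number is unique in each list, and the 5472 distinct regions of the 3 lists (5667 entries) showed 0 inversions between number and position within a chromosome and 0 overlaps between different elements. It was therefore used as the index of the element in the library, an inference from the values. The highest number, 177123, was taken as the library size. Elements beyond it would lower the expected sharing, and elements too poorly covered to be called would raise it. The number of elements on a chromosome was counted with boundaries midway between the last and the first listed numbers of neighbouring chromosomes. The largest such gap was 100 numbers. No region lay on chromosome Y. Starts are printed 1-based.

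Sharing was counted as an overlap of at least 1 bp, which was in every case the same element. Expected sharing was computed by random placement of regions within the span of all listed regions of a chromosome (10000 draws, one-sided), and, added after the files were seen, by the hypergeometric distribution over library numbers. Poisson intervals on counts and exact Clopper-Pearson binomial intervals on shares have a level of 95% and cover counting error only. K562 regions shared with PMA or with HepG2 were compared by an exact McNemar test, and associations inside the third list by Fisher's exact test. Chromosomes were compared by Fisher's exact test between elements listed in 1 list of a pair and not the other. Call rates over all chromosomes were compared by a chi-square test. Clustering was tested by random placement, and widths by a permutation test with 100000 resamples. P-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05. Call rates per chromosome over the library, call rates by library density, neighbours in library numbers and the width classes were added after the files were seen. For density, the library was divided at every 5 listed elements of the other 2 screens, leaving out elements of the list under test, so that the boundaries do not depend on it. Intervals were ranked by elements per Mb and split into tertiles of about equal element number. Boundary elements, and elements before the first or after the last boundary of a chromosome, were left out. A first version, which interpolated the position of every element between listed ones and counted elements in 1 Mb windows, was replaced because the interpolation uses the listed elements themselves; its values are given as an alternative. The width limit of 105 bp is the end of the lowest group of PMA widths, below the first run of 5 absent widths, and 240 bp was read from the width plot. Intervals of ratios of 2 shares are log-normal. The p-values treat library elements as independent, and they compare lists, not replicated samples.

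The procedures were tested on 100 simulated sets of lists with the real lengths and a simulated library of 177123 elements. Counted sharing equalled true sharing in 100% of sets. For K562 and HepG2, 4% of sets without planted sharing and 100% of those with 40 planted elements had p under 0.05. These sets were drawn evenly from all library numbers, as the hypergeometric test assumes. They check the calculation, and not how uneven coverage of the library would affect it. For K562 density, the median ratio was 1.00 without an effect, with 5% of sets under 0.05. A planted ratio of 1.3 gave a median of 1.20 and was detected in 97% of sets, so density ratios are likely to be understated. For K562 chromosome rates, 5% of sets without an effect had any chromosome called, and a planted 1.3-fold excess on chromosome 19 was called in 46%. These simulated rates were adjusted over the 23 chromosomes of K562 alone. The reported tests were adjusted over 69, so both percentages apply to them only roughly.

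Alternatives fixed before the data were examined were a reciprocal overlap of 0.5, midpoints within 1 kb, omission of chromosomes X and Y, merging of regions within 500 bp or 10 kb, random shifts of up to 100 kb or 1 Mb, other neighbour distances, and thinning of all lists to 1341 regions. The rule for regions named in the text was also fixed then. As the lists hold no score, it took the 5 longest regions of each list, the elements in all 3 lists, and the 5 fullest 10 kb windows of each list with ties in genome order, of which a part is printed. Chromosomes named in the text were singled out by their test. Planned comparisons of gene neighbourhoods and of 12 gene lists, of promoter, exon and intron classes, and of GC content and repeats were not run, because the gene table used here is of GRCh38 and no hg19 genome or annotation was used. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.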

Results

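The screens asked which short stretches of human open chromatin hold back transcription. In the ReSE design (repressive ability of silencer elements), a lentiviral library places each genomic insert next to a promoter that drives an inducible caspase. AP20187, a small molecule that dimerizes the caspase, kills cells in which the promoter is active, so inserts that repress it are enriched among survivors. The inserts were recovered by PCR from genomic DNA. The screens covered 3 conditions: K562, a chronic myelogenous leukemia line, HepG2, a hepatocellular carcinoma line, and K562 exposed to PMA, a phorbol ester that drives this line towards a megakaryocyte-like state. Each condition had 2 control and 2 AP20187 libraries, 12 samples in all, and the authors deposited 1 list of called silencer regions per condition, made from all 4 libraries. No list holds a score, a fold or a count per library. The depth of the libraries is therefore unknown here, no replicate error can be given, and every interval below covers counting error only.

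The K562 list held 2664 regions, the HepG2 list 1662 and the list of K562 with PMA 1341, on the same 23 chromosomes (the autosomes and X). Coordinates are those of hg19, the build named in the submitters' processing notes for the K562 and HepG2 samples, and elements shared with the PMA list had the same coordinates. Regions were short: the median width was 191.5 bp in K562 (quartiles 174 and 212), 189 bp in HepG2 (171 and 219) and 186 bp with PMA (166 and 212). Together the regions of a list covered 532934, 349666 and 266363 bp. Every region carries a number that rises with position along each chromosome and that marks the same coordinates in each list, so it was read as the place of the element in the screened library. The highest number was 177123. On that count, 1.50% of the library was listed in K562, 0.938% in HepG2 and 0.757% with PMA.

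Most listed silencer elements were listed in a single condition. Absence from a list is not absence of repression. Without a list per replicate, the sharing between repeats of 1 condition is unknown, so these shares do not measure how specific repression is. Of the 5472 distinct elements in the 3 lists, 4 were listed in every condition. In K562, 5.86% of regions were listed in at least 1 other condition (95% exact binomial interval 4.99 to 6.82%). The share was 5.96% in HepG2 (4.87 to 7.20%) and 9.77% with PMA (8.23 to 11.5%). The 4 common elements were chr5:87987009-87987234 (226 bp), chr7:149697910-149698096 (187 bp), chr8:24471048-24471178 (131 bp) and chr19:50921335-50921502 (168 bp). Independent lists of these lengths would share 0.189 elements across all 3 conditions. No hg19 annotation was used here, so the genes at these positions are not named.

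The first comparison set the 2 cell lines against each other, that is, whether the same inserts repress the reporter in a leukemia line and in a liver carcinoma line. K562 and HepG2 shared 64 elements, which is 2.40% of the K562 list (1.85 to 3.06%) and 3.85% of the HepG2 list (2.98 to 4.89%). Independent draws of library numbers gave 25 shared elements, so the lists shared 2.56 times as many as that expectation (95% Poisson interval 1.97 to 3.27, exact hypergeometric test, one-sided, p = 2.43e-11, adjusted p = 3.65e-11 over the 3 pairs). Placing regions at random along each chromosome gave a mean of 0.704 shared elements and at most 5, a ratio of 90.9. The one-sided p of this randomization test was 0.0001, the smallest that 10000 placements can give. Its outcome was set in advance, as independent draws from the library already share more than any placement did. The ratio depended on the background: placement allows any position, whereas the library holds discrete elements, and the number of elements that were well enough represented to be called is not known.

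The second comparison set the K562 list beside that of K562 given PMA, from separate screens, to see which elements were listed in both. K562 and K562 with PMA shared 96 elements, 3.60% of the K562 list (2.93 to 4.38%) and 7.16% of the PMA list (5.84 to 8.67%). This was 4.76 times the library expectation of 20.2 elements (3.86 to 5.81, exact hypergeometric test, adjusted p = 4.35e-35). In the placement permutation test the ratio was 164 (p = 0.0001). HepG2 and K562 with PMA shared 39 elements, 2.35% of the HepG2 list and 2.91% of the PMA list, or 3.10 times the library expectation of 12.6 (2.20 to 4.24, exact hypergeometric test, adjusted p = 1.19e-09), and 106 times the placement expectation. The PMA arm also differed in handling: cells received AP20187 for 18 hours after 2 days of 10 nM PMA and were sequenced on a HiSeq 4000, whereas the other screens removed dead cells after 1 day, grew the survivors for 5 days and were sequenced on a MiSeq. PMA and these steps cannot be told apart.

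**Figure D1:**
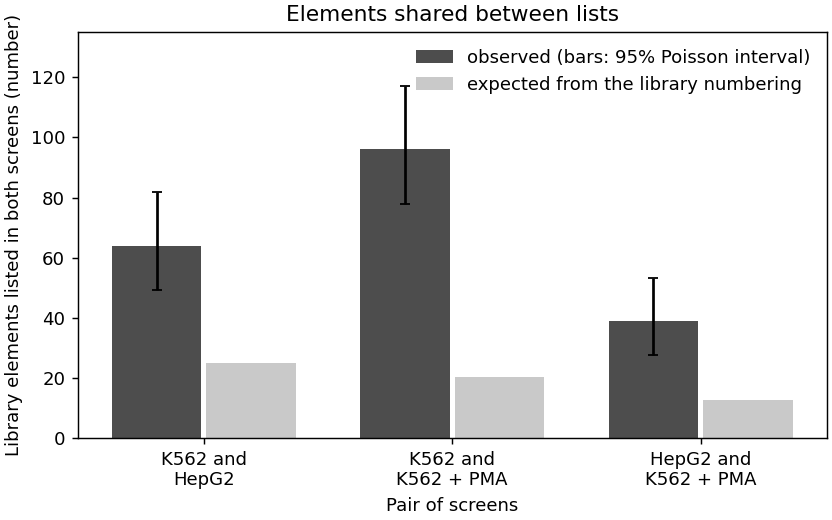
Number of library elements listed in both screens of each pair (dark bars, with 95% Poisson intervals) beside the number expected from independent draws of library numbers (light bars). All 3 pairs lie above expectation, and K562 with K562 + PMA shares most, 96 elements against 20.2 expected.

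The K562 list had more in common with the same line under PMA than with HepG2. Among K562 regions shared with exactly 1 other list, 92 were shared with PMA and 60 with HepG2, a ratio of 1.53 (exact McNemar test, two-sided, p = 0.0117). The PMA list is the shorter one. PMA thus took 60.5% of these regions (52.3 to 68.4%), where the lengths of the 2 lists would give 44.7% (exact binomial test, two-sided, p = 1.12e-04, a test chosen after the lists were seen). The Jaccard index, the shared elements over all elements of a pair, was 2.46% for K562 with PMA, 1.50% for K562 with HepG2 and 1.32% for HepG2 with PMA.

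Sharing was next examined inside the third list, the one outside the pair, whose members were all in the library and callable in at least that screen. Among the 1341 PMA regions, 96 were in the K562 list and 39 in the HepG2 list, and 4 were in both where 2.79 were expected (odds ratio 1.50, 95% interval 0.380 to 4.34, Fisher's exact test adjusted p = 0.356). Among the 1662 HepG2 regions, the odds ratio between K562 and PMA was 2.97 (0.744 to 8.72, Fisher's exact test adjusted p = 0.180). Among the 2664 K562 regions, that between HepG2 and PMA was 1.82 (0.470 to 5.06, Fisher's exact test adjusted p = 0.356). No association was detected against this background, but each count rested on the same 4 elements, and each interval also included the ratio found for that pair over the whole library.

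Over all chromosomes, the listed share of the library varied in K562 (chi-square test over 23 chromosomes, p = 1.13e-04, 4 chromosomes at an unadjusted p under 0.05), and no such variation was detected in HepG2 (chi-square p = 0.319) or with PMA (chi-square p = 0.176). Single chromosomes passed in 2 lists, 1 in K562 and 1 in HepG2. In K562, 1.96% of the chromosome 19 elements were listed (159 of 8097, 1.67 to 2.29%) against 1.48% elsewhere, a ratio of 1.33 (1.13 to 1.55, Fisher's exact test adjusted p = 0.0305 over 69 tests). In HepG2, 0.587% of the chromosome 4 elements were listed (44 of 7497, 0.427 to 0.787%) against 0.954% elsewhere, a ratio of 0.615 (0.456 to 0.829, Fisher's exact test adjusted p = 0.0305). No chromosome passed in the PMA list, where chromosome 13 was lowest at 0.373% (13 of 3488, 0.199 to 0.636%, Fisher's exact test adjusted p = 0.127). With regions within 10 kb merged, neither call held at the threshold although the ratios stayed at 1.29 (1.09 to 1.51, Fisher's exact test adjusted p = 0.102) and 0.622 (0.462 to 0.839, adjusted p = 0.0739). Merged regions were still set against all library elements, which lowers counts most where the library is dense. Chromosome 4 kept its 44 HepG2 regions, and only the rate elsewhere fell, to 0.943%. The merging thus cannot show whether neighbouring regions drove either call. In a direct comparison of elements found in K562 and not HepG2 with those in HepG2 and not K562, 0 of 23 chromosomes differed by Fisher's exact test (lowest adjusted p = 0.702, and 0 at an unadjusted p under 0.05). The comparison of K562 with PMA gave 0 chromosomes as well (Fisher's exact test, lowest adjusted p = 0.303, 2 at an unadjusted p under 0.05: chromosome 16, with 5.14% of K562 against 3.53% of PMA elements, and chromosome 22, with 2.18% against 3.45%).

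**Figure D2:**
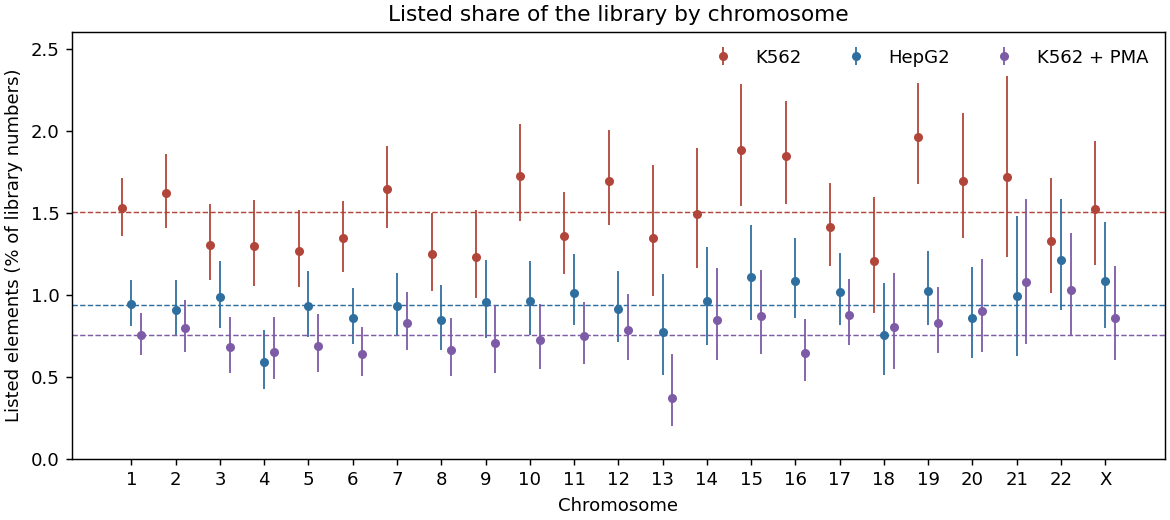
Listed elements as a percentage of the library numbers on each chromosome, for the 3 screens (points, with 95% exact binomial intervals). Dashed lines are each screen's rate over all chromosomes, and the K562 rate on chromosome 19 reaches 1.96% where the line is at 1.50%.

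Elements in densely covered parts of the library were listed more often, in every screen. The library was divided by the number of elements per Mb between listed elements of the other screens. In K562, 1.31% of elements were listed in the sparsest tertile (1.22 to 1.41%), 1.54% in the middle tertile and 1.66% in the densest tertile (1.56 to 1.77%). The densest tertile exceeded the sparsest 1.27-fold in K562 (1.16 to 1.40, Fisher's exact test adjusted p = 7.99e-07), 1.39-fold in HepG2 (1.23 to 1.57, adjusted p = 1.37e-07) and 1.53-fold with PMA (1.34 to 1.75, adjusted p = 1.58e-09). No difference in this gradient passed between screens: the ratio of ratios was 1.09 for HepG2 over K562 (0.938 to 1.28, n = 1662 and 2664 regions, adjusted p = 0.302), 1.20 for PMA over K562 (1.02 to 1.42, adjusted p = 0.0824) and 1.10 for PMA over HepG2 (0.917 to 1.32, adjusted p = 0.302). Of the chromosome 19 elements, 93.8% fell in the densest tertile, and within it chromosome 19 was listed in K562 at 1.22 times the rate of other chromosomes (1.03 to 1.46). Under the interpolated positions that were tried first, that ratio was 1.20 (1.00 to 1.43). Within the sparsest tertile, which held 77.6% of the chromosome 4 elements, chromosome 4 was listed in HepG2 at 0.681 times the rate of the rest (0.470 to 0.985).

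**Figure D3:**
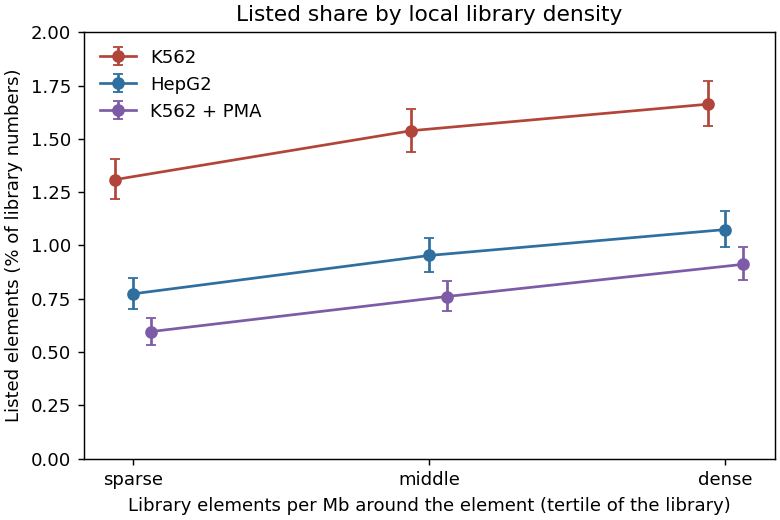
Listed elements as a percentage of library numbers in the sparsest, middle and densest tertiles of the library by elements per Mb, for the 3 screens, with 95% exact binomial intervals. The percentage is higher in the densest than in the sparsest tertile in each screen, from 1.31 to 1.66% in K562.

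Regions of a list lay closer together than random positions, and the excess depended on the background and the distance. In K562, 94 regions had another K562 region within 10 kb, 1.67 times the 56.2 of random placement (permutation test with 10000 placements, one-sided p = 3.00e-04). HepG2 had 36 such regions, a ratio of 1.67 (permutation p = 0.0261), and the PMA list 32, a ratio of 2.24 (p = 0.00230). Counted in library numbers, 382 K562 regions had another within 5 numbers where random draws gave 373 (permutation test, one-sided p = 0.353). The counts were 158 against 150 in HepG2 (permutation p = 0.306) and 116 against 98.1 with PMA (p = 0.106), so no excess was detected at this distance. Against random shifts of up to 1 Mb, neighbours within 10 kb showed no detectable excess (ratios 1.15, 1.08 and 1.45 in K562, HepG2 and PMA, permutation p = 0.175, 0.399 and 0.0856). Within 100 kb the same shifts left a ratio of 1.12 in K562 (758 regions, permutation test, one-sided p = 8.00e-04), 1.19 in HepG2 (349 regions, p = 0.00170) and 1.16 with PMA (229 regions, p = 0.0321). Such shifts allow positions without a library element. By chromosome the library held 28.2 to 138 elements per Mb. On most chromosomes 5 numbers thus spanned, on average, a distance nearer 100 kb than 10 kb, and draws of library numbers showed no detectable excess there. No 10 kb window held 3 or more regions of a list. The first such window with 2 regions in genome order was chr1:21015044-21016182 in K562, chr1:67943423-67945276 in HepG2 and chr1:11152351-11159468 with PMA.

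The 3 lists differed in their shares of short and long regions, while their median widths lay close together. Regions of 150 to 300 bp made up 92.8% of the K562 list (91.7 to 93.7%), 86.7% of the HepG2 list (85.0 to 88.3%) and 83.9% of the PMA list (81.8 to 85.8%). Regions over 300 bp formed 3.57% of the K562 list, 7.46% of the HepG2 list and 5.67% of the PMA list. The odds of such a width were higher among elements listed in HepG2 and not K562 than among those in K562 and not HepG2 (odds ratio 2.23, 1.67 to 2.97, Fisher's exact test adjusted p = 4.02e-08). They were also higher with PMA than in K562 (odds ratio 1.66, 1.19 to 2.31, Fisher's exact test adjusted p = 0.00361). Regions of at most 105 bp numbered 58 with PMA (4.33%, 3.30 to 5.56%) against 1 in K562 and 2 in HepG2, and 32 of the 58 were exactly 101 bp and 18 were 102 bp. The longest regions were chrX:139865335-139866831 in K562 (1497 bp), chr20:4679720-4680955 with PMA (1236 bp) and chr6:31509523-31510437 in HepG2 (915 bp), each in that list alone. The next longest were chr3:37284390-37285183 (794 bp) in K562, chr9:90001900-90002782 (883 bp) in HepG2 and chr7:5569187-5569883 (697 bp) with PMA. No difference in median width was detected between shared elements and the others. The median of shared elements minus that of the others was -3.5 bp in K562, -1.0 bp in HepG2 and 1.0 bp with PMA (permutation test, two-sided, adjusted p = 0.929 in each). Medians do not show the extremes. Regions outside 150 to 300 bp were shared at 9.33% in K562 (18 of 193) against 5.58% of those within it, at 4.98% in HepG2 (11 of 221) against 6.11%, and at 6.48% with PMA (14 of 216) against 10.4%. None of these differences passed (Fisher's exact test, two-sided, p = 0.0386, 0.647 and 0.0802, adjusted p = 0.240, 0.785 and 0.240 over 9 tests chosen after the widths were seen). Of the 58 PMA regions of at most 105 bp, 0 were shared.

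**Figure D4:**
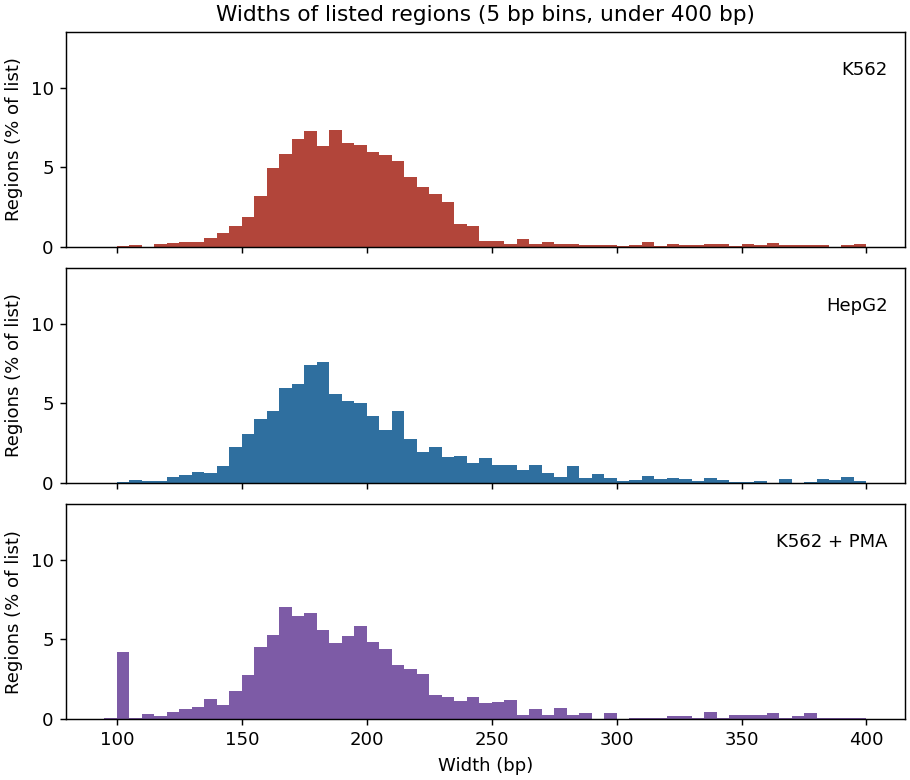
Widths of listed regions in bp (horizontal axis, 5 bp bins, regions under 400 bp) as a percentage of each list (vertical axis), for K562, HepG2 and K562 + PMA. The PMA list has a separate group of regions just above 100 bp, 58 of at most 105 bp, and the K562 list falls off sharply above about 240 bp.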

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

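The tests of widths, the limits of 105 and 240 bp and the tests of a general shift were chosen after the widths were seen. The other tests in this part were stated before their results, but the limits of 220 and 260 bp, and the decision that the size selection test settles nothing when its ratio is under 1, came after. Each result was picked out because the odds of a width differed between screens in a test of the difference itself (Fisher's exact test, two-sided), among elements in 1 list of the pair and not the other.

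Elements of at most 105 bp had an odds ratio of 125 for PMA over K562 (21.6 to 5040) and of 37.8 for PMA over HepG2 (9.96 to 320), with 58 such elements under PMA, 1 in K562 and 2 in HepG2. The limit was set from the PMA widths, and with widths under 120 bp, also chosen after they were seen, the PMA share over that of the other lists together fell from 62.4 to 13.8 times. The tables argued against 1 genomic cluster, since the 58 elements lay on 20 chromosomes with at most 12.1% on any of them. A large excess that extends to 106 to 149 bp was argued against relative to HepG2, as the PMA share there was 1.07 times that of HepG2 (0.803 to 1.42). A smaller general shift towards short elements stays open relative to HepG2. The width quartiles were 166 and 212 bp with PMA against 171 and 219 bp in HepG2. A general shift also stays open relative to K562, where the ratio at 106 to 149 bp was 1.68 (1.26 to 2.24). Sequencer or read length also stays open: 0% of the 58 were listed in a MiSeq screen against 10.2% of the other 1283 PMA elements, but as the MiSeq lists hold so few elements of this width, this restates the excess, and sequencer, handling and PMA, which changed together, cannot be told apart.

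Elements over 240 bp made up 6.83% of the K562 list, 17.2% of the HepG2 list and 12.6% of the PMA list, with odds ratios of 2.94 for HepG2 over K562 (2.39 to 3.61), 2.05 for PMA over K562 (1.62 to 2.58) and 0.690 for PMA over HepG2 (0.557 to 0.853). A candidate explanation is that the size selection of PCR products differed between screens: HepG2 or PMA elements over 240 bp were listed in K562 at 0.593 times the rate of shorter ones (0.351 to 1.00, 15 of 451 against 141 of 2513). That ratio follows from any lack of long elements in K562, and its interval included 1 at 220 bp (0.836, 0.567 to 1.23) and at 260 bp (0.652, 0.357 to 1.19), so it leaves size selection open. Calls of long elements that do not repeat cannot be told apart either, because only 4 of 286 such HepG2 elements were listed with PMA, 0.550 times the rate of shorter ones (0.197 to 1.53). A difference between the cell lines in the length of repressing elements also stays open and was not tested.

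Elements of 106 to 149 bp had an odds ratio of 1.63 for HepG2 over K562 (1.19 to 2.22, Fisher's exact test adjusted p = 0.00296) and of 1.77 for PMA over K562 (1.28 to 2.45, adjusted p = 8.88e-04). Elements over 300 bp had an odds ratio of 2.23 for HepG2 over K562 (1.67 to 2.97) and of 1.66 for PMA over K562 (1.19 to 2.31).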

How the results depend on the processing

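No paired analysis was possible because each deposited list pools the replicates of its condition, and for the same reason no replicate could be left out. The stricter part of each list by score was not run, since the lists hold no score, and the gene, location and sequence alternatives were not run for want of hg19 references. The counts of shared elements moved by less than 1.5 times with midpoints within 1 kb, omission of chromosomes X and Y and merging within 500 bp. Reciprocal overlap and omission of elements of 105 bp or less could not change them. Every overlap was the same element with the same coordinates, and none of the elements of 105 bp or less was shared. This omission was chosen after seeing the data, as were library numbers, list lengths, merged chromosome rates, 1 Mb shifts read at 100 kb and all density settings. Thinning all lists to 1341 regions lowered the sharing of every pair, as shorter lists must. It fell to 25.1 for K562 and HepG2, to 48.5 for K562 and PMA, and from 39 to 31.1 for HepG2 and PMA. The ratio of observed to expected sharing kept its direction and its side of the threshold under each background. Only library numbers test it, since placement and shifts allow positions without a library element. For K562 and HepG2 it fell from 90.9 (placement) to 42.2 (100 kb shifts) and 2.56 (library numbers). For K562 and PMA it fell from 164 to 75 and 4.76, and for HepG2 and PMA from 106 to 51.9 and 3.10. The ratio of K562 regions shared with PMA to those shared with HepG2 ranged from 1.45 to 1.99 over its 7 alternatives, with p between 1.12e-04 and 0.0316. Among these, reciprocal overlap and omission of elements of 105 bp or less could not change it. The odds ratios inside the third list ranged from 1.35 to 2.97 and stayed above the threshold, with adjusted p from 0.180 to 0.542. Merging regions within 10 kb took the count of departing chromosomes from 1 to 0 in K562 and from 1 to 0 in HepG2. As the library elements were not merged with them, this does not show that neighbouring regions drove the calls. The chromosome comparisons between lists gave 0 with all regions of each list and with merged regions. For clustering, with 1 kb in place of 10 kb the ratio was 1.75 in K562 and 2.76 with PMA, no longer past the threshold, and 0.934 in HepG2, a reversal that rests on 2 regions. With shifts of up to 1 Mb the 10 kb ratios were 1.15, 1.08 and 1.45 in K562, HepG2 and PMA, and with library numbers 1.02, 1.06 and 1.18. None was past the threshold, and the cause was not tested. Within 100 kb the ratios were 1.51, 1.72 and 1.70 against placement and 1.12, 1.19 and 1.16 against 1 Mb shifts, all past it. Placement and shifts allow positions without a library element, so neither separates this excess from uneven spacing of the library. The draws of library numbers allow for that spacing. Their 5 numbers spanned, on average, nearer 100 kb than 10 kb on most chromosomes, and no excess was detected with them. The density ratios kept direction and call under every other setting, between 1.19 and 1.64, and were 1.50, 1.51 and 1.64 in K562, HepG2 and PMA with interpolated positions. Depth per library is unknown, so it cannot be said which elements were too thinly covered to be called.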

Other observations

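The tests in this part were all chosen after the lists were seen.

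Sharing between screens exceeded random draws at the same element, and no excess was detected among its neighbours. Pairs of different elements within 5 library numbers of each other, 1 listed in each screen, numbered 251 for K562 and HepG2 where random draws of library numbers gave 249 (220 to 281 in 95% of 1000 draws). For K562 and PMA there were 218 against 202 (174 to 231), and for HepG2 and PMA 116 against 125 (103 to 147). The same element was listed in both screens 2.57, 4.77 and 3.09 times as often as in these draws. How well each element was covered is unknown, so these counts do not tell repression by an element from its coverage in the library.

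If each pair of lists were drawn at random from 1 pool, the overlap gives the size of that pool. It came to 69181 elements for K562 and HepG2 (95% interval 54175 to 89831), 57147 for HepG2 and PMA (41804 to 80365) and 37213 for K562 and PMA (30473 to 45942), against 177123 numbered elements.

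Each pair of lists shared more elements than the library expectation. One candidate explanation is a smaller pool of callable elements common to the 3 screens, which was argued against as the whole cause by the K562 regions, shared with PMA and HepG2 out of proportion to list lengths (exact binomial test, two-sided, p = 1.12e-04), but not by the HepG2 regions shared with exactly 1 list, 36.8% of them with PMA where lengths give 33.5% (p = 0.515), so that it may contribute to every pair. A common sequencer was argued against as the reason for the order of the pairs, as K562 and PMA, from different sequencers, reached 4.76 times expectation (3.86 to 5.81) and the 2 MiSeq screens 2.56 times (1.97 to 3.27). The values went with the cell line as a factor. Of the PMA regions shared with exactly 1 list, 72.4% were shared with K562, where list lengths give 61.6% (exact binomial test, two-sided, p = 0.0135). This test and that on the K562 regions count the same 92 elements, so they are not separate support. A first comparison used the ratios to expectation, whose intervals overlapped for K562 and PMA and for HepG2 and PMA (3.86 to 5.81 and 2.20 to 4.24). Overlap of 2 intervals is not a test of their difference, so that comparison decides nothing. Whether the K562 screens had a virus preparation or an infection in common is not stated in the labels and was not tested.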
